A study of Mus musculus with 13 samples.

How the data were processed

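RNA of mouse embryonic fibroblasts, of fibroblasts at successive days of reprogramming by doxycycline (Dox)-inducible factors, and of induced pluripotent stem (iPS) cells was measured on 13 Affymetrix mouse exon arrays, 1 array per condition. The values used were the authors' deposited log2 values per transcript cluster, made by RMA at the gene level in Affymetrix Expression Console, per the submitters' processing notes, which name the mm9 build and give no software version. RMA corrects background, normalizes arrays to each other and summarises the probes of a cluster, so a level cannot be compared between clusters, and low values are compressed. The log base is not given in the sources used here and was taken as 2 from the range of the values, 0.461 to 14.3. The table held 23332 clusters. Gene symbols came from the platform annotation: 14996 clusters had 1 symbol, 1019 had several and 7317 had none, and only clusters with 1 symbol were named. Of the symbols, 14941 were updated by gene identifier to those of the GRCm38.p6 annotation. That build differs from the one the notes name, so no coordinates are given. Where a gene had several clusters, the one with the highest mean over the arrays was used.

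The arrays fell into 3 untreated fibroblast arrays (parental fibroblasts, line 6C at day 0 and line 1B at day 0), 2 arrays at 5 days of Dox (6C and 1B), 2 arrays of Dox-independent iPS cells and 6 conditions of 1 array. The labels name no separate cultures of one condition, and the untreated arrays come from different lines. For iPS against untreated cells, the p-values therefore rest on the spread between these arrays. In the 6C series, with 1 array per day, they rest on the scatter around a curve fitted over the days. At day 5 they rest on how the change differs between the 2 lines. The array names gave 4 runs: run 2 held parental fibroblasts, primary iPS cells and 6C at days 2, 5, 11 and 16; run 1 held 6C at days 0 and 21; run 3 held the 1B arrays; run 4 held 6C at day 8 and the secondary iPS cells. The name of the day 0 array of 6C speaks of day 2 without Dox and that of the day 8 array of day 9; the sample labels were followed. The iPS samples are called Dox independent, per the labels, while their agent label names Dox; which holds was not settled, and it bears on the levels of the inducible factors in them. Array medians ranged from 6.34 to 6.67 and 75th percentiles from 8.50 to 9.06, with both lowest values in 6C at day 0; the medians of the other arrays lay 0.03 to 0.33 above its median. The number of arrays limits the precision of every value.

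The tests were fixed before the data were examined. Using limma 3.58.1 in R 4.3.3, iPS cells were compared with untreated fibroblasts (2 against 3 arrays), called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. The 6C series (8 arrays, days 0 to 21 and the iPS cells at day 30) was fitted with a polynomial of day of degree 3, called at an adjusted p under 0.05 of the moderated F test and a fitted change from day 0 of at least 2-fold at a sampled day. A called cluster was counted as higher or lower by the sign of its fitted change at the last day, with no fold required on that day. The onset of a called cluster was the earliest sampled day on which its curve lay over 2-fold from day 0. Rises and falls by onset were named by the direction on that day. Day 5 was compared with day 0 in both lines with line as a block (4 arrays). Single arrays were compared without a test, by counts of clusters over 2-fold apart. After withdrawal of Dox in 1B, a cluster was said to have returned if it kept under 0.5 of its day 5 change. This included clusters that had passed day 0 in the other direction. Progress was the slope, through the origin, of an array's difference from the parental fibroblasts on that of the primary iPS cells, so that 0 is the parental array and 1 the primary iPS array.

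For 22 gene lists fixed beforehand, camera was used with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. For single arrays, a list's median was placed among those of 10000 random lists matched on mean expression. Named genes were chosen by a rule fixed beforehand: the 10 largest rises and falls between iPS and untreated cells among called clusters whose arrays did not overlap; the 3 largest changes per onset day and direction; the 10 largest day 5 changes each way by the smaller of the changes in the lines; the 8 largest changes each way in 1B; the 5 largest differences each way between the iPS arrays and between each line and the parental cells; the reprogramming factors; and up to 6 members per list and comparison. RIKEN and predicted names were left out. Alternatives were other scalings, a filter on low values (14365 clusters left), other curves, thresholds, blocks and baselines, and each array left out in turn.

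The fits were tested on simulated data of 23332 clusters with 200 changed. In the time course each simulated change was a straight line in day that reached its full size at day 30. Early steps and rises confined to mid-series were not simulated, so the recovery of such patterns is not known. With residual SDs as fitted, 88.0% of 32-fold, 40.0% of 8-fold and 24.0% of 4-fold changes were recovered for iPS against untreated cells, and 80.0%, 42.0% and 10.0% in the 6C time course; no 2-fold change was recovered. The day 5 fit, with these SDs, recovered none at any size. The 32-fold size and a simulation with moderated SDs were added after a first test, without them, had recovered few changes. With moderated SDs 98.0%, 84.0% and 54.0% were recovered for iPS against untreated cells (4 false calls) and 92.0%, 54.0% and 10.0% in the time course (5 false calls). The day 5 fit then recovered 58.0% of 4-fold changes and 100% of larger ones, with 36 false calls, so its error rate depends on how the spread is modelled.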

Results

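The study followed mouse embryonic fibroblasts to induced pluripotency. Its 6C and 1B lines carry reprogramming factors that doxycycline (Dox), given at 1.5 µg per ml, turns on. The 6C series had arrays at days 0, 2, 5, 8, 11, 16 and 21 and of secondary iPS cells at day 30. The 1B series had arrays at day 0, at day 5 and after 5 further days without Dox. Parental fibroblasts and the primary 6C iPS cells had 1 array each. There were no replicate arrays of a condition. Values are deposited log2 RMA values.

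The first comparison asked how iPS cells differed from untreated fibroblasts. Genes of the pluripotency list were among the largest rises. Dppa4 was higher by 8.84 on the log2 scale (SE 0.35), Tdgf1, a Nodal co-receptor, by 8.32 (SE 0.69), Bex1, which is outside that list, by 7.76 (SE 0.76), and the transcription factor Nanog by 7.22 (SE 0.39). Pou5f1, which encodes Oct4, was higher by 7.05 (SE 0.55). Among the largest falls were Svep1 (-4.99, SE 0.48), the gap junction gene Gjb2 (-4.85, SE 0.60), the interleukin receptor Il1r1 (-4.71, SE 0.76) and the collagen Col6a3 (-4.32, SE 0.61). Nr0b1, Zfp42, Trh, Pla2g1b and Utf1 were the other genes of the 10 largest rises, and Ptx3, Il1rn, Adamts1, Prelp, Osmr and Cbr2 those of the 10 largest falls.

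Of 30 pluripotency genes measured, 25 rose and none fell, and 28 rose when adjusted over the list alone. Of 25 epithelial genes 17 rose (23 adjusted over the list alone), among them the adhesion genes Epcam (6.88, SE 0.35) and Cdh1 (5.71, SE 0.34). Of 33 mesenchymal genes 11 fell (30 adjusted over the list alone), with Col6a1 at -3.95 (SE 0.83) and Pdgfrb at -3.41 (SE 0.75). The iPS arrays stood apart on this list, the secondary one a median of 2.17 above the primary one. In the TGF-beta list 11 of 19 genes fell, and 14 adjusted over the list alone. In the cell cycle list 18 of 26 rose, in the chromatin list 16 of 26 and in the germline list 10 of 15, with 22, 19 and 12 adjusted over the list alone. Dazl, a germ cell RNA-binding protein gene, was higher by 4.30 (SE 0.26) and Hormad1 by 5.44 (SE 0.44). By camera with the preset correlation, the pluripotency (adjusted p = 4.12e-29), epithelial (4.50e-18), mesenchymal (4.55e-14), TGF-beta (6.38e-07), cell cycle (1.85e-15), chromatin (4.07e-13) and germline (5.19e-12) lists shifted. With an estimated correlation the pluripotency list kept an adjusted p = 0.028, and the others had adjusted p = 0.088, 0.43, 0.43, 0.43, 0.054 and 0.053 in that order.

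In all, 1269 of 23332 clusters were higher and 775 lower in iPS cells by limma. The lower count was 1299 with quantile normalization, 1295 with centring and 1450 with the filter on low values. Over all clusters, called or not, the groups did not overlap for 10341, where chance gives 20%. In run 2, which held both groups, 3294 clusters were over 2-fold higher and 4432 lower in primary iPS cells than in parental fibroblasts, without a test. The calls depended on each array: without the primary iPS array 79 were higher and 1 lower, without 1B day 0 137 and 4, without the parental array 312 and 39, without 6C day 0 339 and 168, and without the secondary iPS array 448 and 480.

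The 6C series asked when these changes occurred. Pou5f1 stood at 4.74 at day 0, 12.57 at day 2 and 13.28 at day 5; its curve did not pass the test (adjusted p = 0.14). The clusters of Klf4 and Myc, which encode other reprogramming factors, lay between 8.54 and 10.02 and between 10.44 and 11.49 in this series. That of Sox2 lay at 5.08 at day 0, 9.45 at day 21 and 13.03 in iPS cells (adjusted p = 0.0052 by limma's F test). At day 11 all 4 of these factor genes were over 2-fold above day 0. The day 0 array itself had a median of -1.31 against parental cells over these 4 genes. Where the probes lie relative to the introduced sequences was not analysed here. Epithelial genes came early: 18 of 25 were called as rising (23 adjusted over the list alone), each with its onset by day 5. Epcam went from 4.87 at day 0 to 9.59 at day 5 and 12.39 at day 8, and Cdh1 from 5.80 to 9.74 and 10.86.

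Pluripotency genes were spread over the series. Of 25 that rose (28 adjusted over the list alone), 15 had their onset by day 5, among them Nanog, Nr0b1 and Tdgf1, and 7 at days 16 or 21, among them Dnmt3l and Dppa2. Nanog was 5.54 at day 0, 7.75 at day 5, 10.12 at day 8 and 12.42 at day 21. Dppa2 was 1.59 at day 0, 3.31 at day 21 and 8.12 in iPS cells. Of 8 germline genes called (11 adjusted over the list alone), 4 had their onset at day 30, including Dazl and Stk31, 3 at days 16 or 21 and 1 by day 5. Of 33 mesenchymal genes 16 ended lower (29 adjusted over the list alone), with a median onset of day 11. Col6a3 had its onset at day 5, Pdgfrb at day 8 and Snai2 at day 11. In the chromatin list 10 of 26 rose (19 adjusted over the list alone). No cell cycle gene passed limma's F test over the whole curve (12 of 26 adjusted over the list alone), where 5743 of all clusters had an unadjusted p under 0.05. In the contrasts of single fitted days against day 0, 2 cell cycle genes were higher at day 21 and 5 at day 30 (13 and 16 adjusted over the list alone). The list's day 30 shift had an adjusted p = 9.67e-09 by camera (adjusted p = 0.41 with an estimated correlation).

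**Figure D1:**
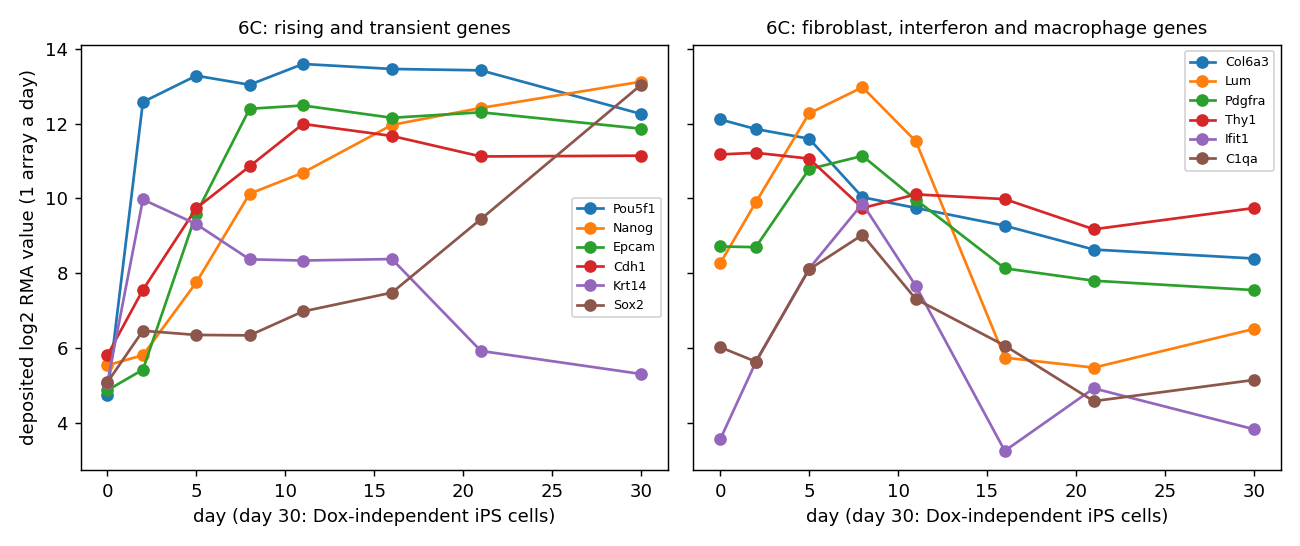
Deposited log2 values (vertical axis) of 12 genes against day (horizontal axis) in the 6C series, 1 array per point, with the iPS cells at day 30. Pou5f1 stood at 12.57 by day 2, Nanog reached 12.42 at day 21, and Lum rose to 12.97 at day 8 before standing at 5.75 at day 16.

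Of 23332 clusters 1485 were called in the time course, 904 above and 581 below day 0 at day 30, with no fold required at day 30. By onset day, 65.1% of the 1074 rises and 18.0% of the 411 falls had begun by day 5. Rises and falls were named here by the direction at onset, so a rise could end below day 0. By day 21 the shares were 86.2% and 86.9%. The day 0 array was the dimmest of the series, and with quantile normalization the shares begun by day 5 were 47.6% and 29.3%. With the mean of the untreated arrays as day 0, an alternative chosen after seeing the data, they were 52.4% and 16.8%, and the calls split into 49.8% above day 0 in place of 60.9%. Without the day 0 array the change was taken from day 2, and 98 clusters were called above day 2 and 53 below it. Without the iPS array the direction was taken at day 21, and 156 clusters were called above day 0 and 38 below.

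Some genes were high only in the middle of the series. The interferon response list had its highest median at day 8, 3.18 above day 0, with 1.71 at day 5, 2.04 at day 11 and 0.09 at day 16. Ifit1 stood at 3.56 at day 0, 9.86 at day 8 and 3.25 at day 16. The parental array, too, stood above 6C day 0 on this list: 6C day 5 lay 0.26 above parental cells, and 6C day 0 lay -1.49 from them. Of 14 members 2 were called as ending higher and 1 lower (8 and 1 adjusted over the list alone). Ending higher or lower was the sign of the fitted curve at day 30, so it does not mean a lasting change. In the iPS array the list's median lay 0.19 above day 0, with 2 of 14 members over 2-fold higher. The list's fitted day 11 shift had an adjusted p = 4.70e-07 by camera (adjusted p = 0.31 with an estimated correlation). Markers of macrophages and blood moved with it: their median was 1.75 at day 8 and -0.09 at day 16, and C1qa went from 6.03 at day 0 to 9.03 and 6.07. The keratinocyte list was not confined to the middle. Its median lay 0.99 above day 0 at day 2, 2.31 at day 11, 1.02 at day 16 and 0.55 at day 21. In the iPS array it lay 0.15 above day 0. Of 19 keratinocyte genes 6 were called, 3 ending higher and 3 lower (6 and 3 adjusted over the list alone). Dsg3 was 4.29 at day 0, 9.62 at day 11 and 3.73 in iPS cells, and Krt1 was 5.08 at day 0, 9.02 at day 5 and 4.57 in iPS cells.

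Day 5 of Dox was compared with day 0 in both lines. Pou5f1 had the largest shared rise, from 4.74 to 13.28 in 6C and from 5.58 to 13.16 in 1B. Cyp4f39, Mal, Nr0b1, Tek, Podxl, Fetub, Krt16, Aqp3 and Avil followed; Mal, a membrane trafficking gene, went from 4.89 to 10.83 and from 4.86 to 11.04. Gjb2, Coch, Acta1, Cnn1 and Inhba led the shared decreases, with Gjb2 going from 10.72 to 6.90 and from 11.45 to 7.10. No cluster passed the test by limma (lowest adjusted p = 0.34), while 1770 had an unadjusted p under 0.05. With each array centred on its median, 334 higher and 259 lower clusters were called.

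Line by line, 3407 clusters were over 2-fold higher and 1367 lower in 6C, and 2215 higher and 2955 lower in 1B. With quantile normalization, 6C had 2144 higher and 2043 lower, and 1B 2539 higher and 2676 lower. With centring, 1B had 2769 higher and 2506 lower, so which direction was more frequent in 1B depended on the scaling. Both lines were higher for 888, where independent changes give 323, and both lower for 277, where they give 173. In opposite directions, 6C was higher and 1B lower for 468 (431 if independent), and 6C lower and 1B higher for 82 (130 if independent). Across clusters, which are not independent replicates, Pearson's r was 0.22 and Spearman's rho 0.15. Epithelial genes had a median change of 1.69 in 6C and 2.16 in 1B, each above the matched random lists (percentile 100). The mesenchymal median was -0.05 in 6C (percentile 0.01), below the matched lists although near 0, and -3.37 in 1B (percentile 0). The cell cycle median was 0.33 in 6C (percentile 33.9) and 1.63 in 1B (percentile 100). Postn, a matrix gene, went from 12.22 to 12.13 in 6C and from 11.05 to 5.56 in 1B. Adjusted over the list alone, the joint test had 16 of 25 epithelial, 10 of 19 keratinocyte, 8 of 30 pluripotency, 3 of 18 neural, 2 of 14 glycolysis, 1 of 16 endothelial and 1 of 4 reprogramming factor genes higher, and 2 of 19 TGF-beta and 1 of 15 muscle genes lower. By camera the epithelial (adjusted p = 3.64e-16), keratinocyte (1.78e-10), cell cycle (4.07e-07), chromatin (4.07e-07), pluripotency (9.52e-04), oxidative phosphorylation (0.017) and reprogramming factor (0.032) lists shifted upward. The mesenchymal (1.32e-09), TGF-beta (6.57e-06) and BMP (0.032) lists shifted downward. None of these kept its call: oxidative phosphorylation and BMP had adjusted p = 0.73 and the others adjusted p = 0.68 with an estimated correlation. In simulation with moderated SDs this joint fit made 36 false calls. The shift of the reprogramming factor list is no independent finding, since Dox turns on reprogramming factors in these lines. Its median change was 1.15 in 6C (percentile 98.95) and 0.067 in 1B (percentile 54.5). Of its 4 genes, 3 were over 2-fold higher and 0 lower in 6C, and 1 was higher and 1 lower in 1B.

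Withdrawal of Dox in 1B asked which day 5 changes lasted. Pou5f1 fell back from 13.16 to 6.41 and Nanog from 10.82 to 6.55. Of 2215 clusters over 2-fold higher at day 5, 1816 returned (82.0%), and of 2955 lower 2123 returned (71.8%). The 1B day 5 array both chose these clusters and measured their change, which biases these shares. For clusters chosen in 6C the shares were 66.1% and 54.2%, though most of these had not changed over 2-fold the same way in 1B. Over clusters that changed over 2-fold the same way in both lines, a selection chosen after seeing the data, the shares were 81.4% and 63.9%. That selection also uses the 1B day 5 array. In all these shares, a cluster that had passed day 0 in the other direction counted as returned. Over all clusters, 788 were over 2-fold higher and 1729 over 2-fold lower after withdrawal than at day 0. Mesenchymal genes returned in 26 of 30 cases: Postn stood at 11.07 and Pdgfrb at 11.05, where day 0 had 11.05 and 11.47, while Lum stood at 3.85 against 7.80. Epithelial genes returned in 13 of 21 cases. Cldn4, a tight junction gene, was 7.76 at day 0, 11.08 at day 5 and 11.14 after withdrawal, and Spint2, a protease inhibitor gene, was 8.29, 11.98 and 10.92. All 23 cell cycle genes higher at day 5 returned, and the list's median lay at -1.25 against day 0.

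**Figure D2:**
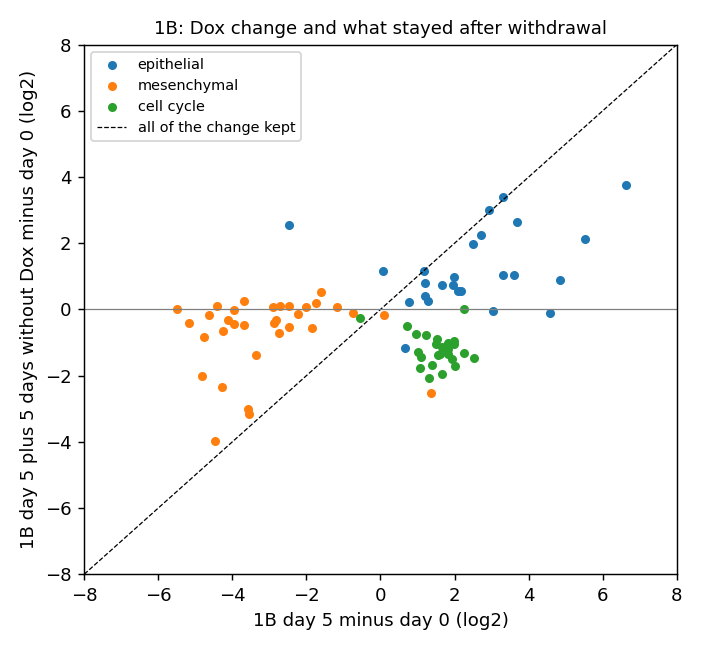
Change after 5 days of Dox (horizontal axis, log2) and after 5 further days without Dox (vertical axis, log2), both against 1B day 0, for genes of the epithelial, mesenchymal and cell cycle lists, 1 point per gene. Points on the dashed line kept all of their change; of the genes over 2-fold lower (mesenchymal) or higher (epithelial) at day 5, 26 of 30 and 13 of 21 kept under 0.5 of it.

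Progress from parental fibroblasts to primary iPS cells was taken over 3294 clusters higher and 4432 lower in iPS cells. In 6C it was 0.34 and 0.26 at day 5, 0.57 and 0.45 at day 11, and 0.63 and 0.54 at day 16. It was 0.57 and 0.67 at day 21, and 0.79 and 0.67 in secondary iPS cells. Over the higher clusters, day 21 thus stood no further than day 16. The other untreated arrays stood at 0.048 and 0.39 (6C day 0) and at 0.14 and 0.21 (1B day 0); an untreated array other than the parental one lies above 0 without any progress, since the clusters were chosen by their difference from the parental array. 1B at day 5 stood at 0.53 and 0.70, and after withdrawal at 0.14 and 0.36.

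**Figure D3:**
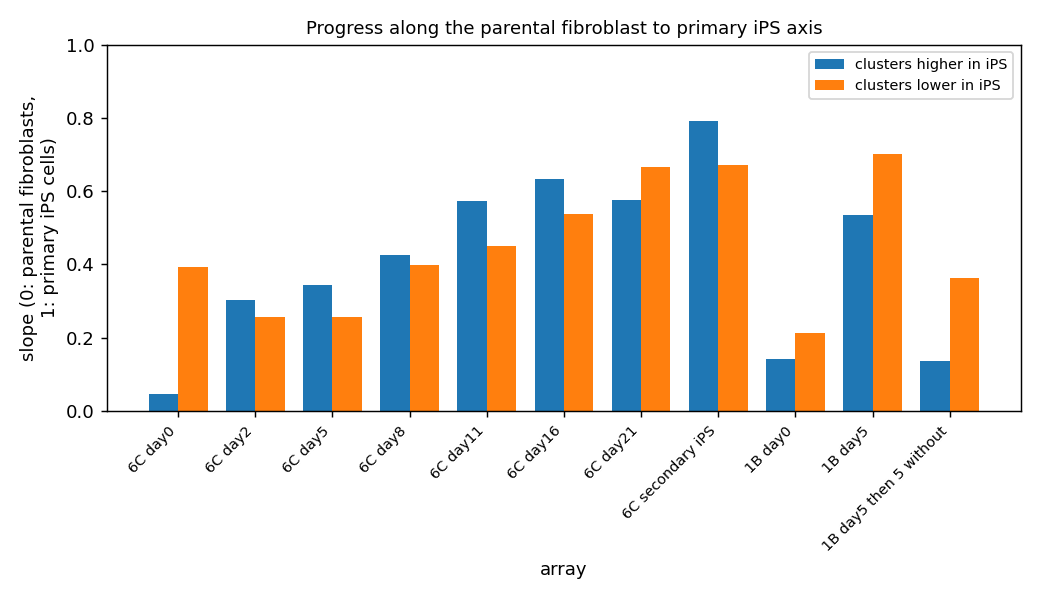
Progress (vertical axis, slope with 0 for parental fibroblasts and 1 for primary iPS cells) of 11 arrays (horizontal axis), with 1 bar for clusters higher and 1 for clusters lower in primary iPS cells. 1B stood at 0.53 and 0.70 at day 5 and at 0.14 and 0.36 after withdrawal.

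The iPS arrays differed over 2-fold at 3566 clusters, 1852 of them higher in secondary cells. Usp26 (10.15 against 5.22), Lypd10, Aspn, Car4 and the matrix gene Postn (10.77 against 6.24) were the largest differences upward, and Gpx2, Olfr888, Adap1, Parvb and Olfr199 the largest downward. The mesenchymal list had a median 2.17 higher in the secondary cells (percentile 100) and the pluripotency list one of -0.20 (percentile 0.8). The untreated arrays differed from each other at 4129 (6C and parental), 2781 (1B and parental) and 3159 (6C and 1B) clusters. Thbs4 and Comp, matrix genes of cartilage and tendon, stood at 11.82 and 11.90 in parental cells and at 5.86 and 6.34 in 6C at day 0.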

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

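Of the tests under this heading, that of the mixture was set before its result was seen. The others here, that of the day 8 array included, were chosen after. Several results moved in opposite directions in the lines at day 5, over 2-fold in each; with 1 array per condition these differences were not tested. The interferon list changed by 1.71 in 6C and -1.04 in 1B, a difference of 2.76. The difference between the change in 6C and that in 1B was 8.47 for Lum, 6.33 for Gbp2, 6.31 for Tgfbi, 5.55 for Tgfbr3, 6.72 for Ifit1, 5.64 for Pdgfra, 3.60 for Stat2 and 3.94 for Ctss. Of 394 list members, 19 moved this way, and these are the 8 with the largest smaller change.

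Interferon and macrophage transcripts were higher in 6C at days 5 to 11. A difference between runs is argued against, since within run 2 the interferon median at days 5 and 11 lay 1.61 above that at days 2 and 16 (quartiles 0.83 and 2.22; higher for 14 of 14 genes). Macrophages in the culture stay open as a possible explanation. Of 15 markers (Gata1 left out) 11, or 73.3%, were over 2-fold higher, but this count restates the pattern and weighs neither for nor against them. Among the abundant markers Ctss stood at 10.56 and Cd68 at 10.54 at day 8, though Cd68 also stood at 9.62 in primary iPS cells. A response to Dox shared by the lines also stays open, as the interferon median in 1B was -1.04 but rests on single arrays.

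The secondary iPS array held more fibroblast transcripts than the primary one. Run 4 stays open: its other array, day 8, lay -0.13 from the mean of days 5 and 11 on the mesenchymal list (quartiles -0.64 and 0.22), where secondary exceeded primary cells by 2.17, but 1 array of a changing series does not exclude it. Fibroblasts mixed into the secondary cells are a candidate explanation. Over 115 clusters abundant in fibroblasts and at least 3 lower (log2) in primary iPS cells, the secondary array had a median of 21.0% of the fibroblast level (quartiles 15.2% and 29.6%), and the interquartile range of its log2 was 1.07 times the largest found between 1 untreated array and the mean of the others (0.97 against 0.90). Incomplete silencing in the iPS cells themselves was not tested.

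1B stood further along the fibroblast to iPS axis at day 5 than 6C. For clusters higher in iPS cells, the difference was 0.19. It was 0.049 when each day 5 array was set against the untreated array of its run (for 6C, the parental array). Against day 0 of its own line it was 0.096. The SD of progress over the untreated arrays was 0.072. That SD counts the parental array as 0, the origin of the axis, so it is no measure of noise. For clusters lower in iPS cells, the difference of 0.45 was 0.23 against the array of the same run and 0.63 against day 0 of the same line, with an SD of 0.20; 1B had moved by 0.49 and 6C by -0.14 from its own day 0. The result depended on the baseline, and for 6C day 0 lies in another run. Run and baseline cannot be told apart from a difference between the lines, because each line has 1 array per day.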

How the results depend on the processing

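Alternatives with the mean of the untreated arrays as day 0, with quantile normalization of the onset days and gene lists, with day 8 left out of the gene lists, with clusters over 2-fold in both lines and with the called clusters without 6C day 0 were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers, other than pairing day 5 with day 0 within each line; by limma 0 clusters were called there with line as a block (1770 with an unadjusted p under 0.05) and 0 without it. Run as a random block could not be estimated for iPS against untreated cells, since 5 arrays span 4 runs. Counts changed with the scaling and with the filter on low values; the cause was not tested, except where an alternative tests fewer clusters or arrays.

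For iPS against untreated cells, the higher count stayed within 1.5 times of 1269 under the scalings, filter and trend, while the lower count of 775 was 1299 with quantile normalization, 1295 with centring and 1450 with the filter. Within run 2, 3294 clusters were over 2-fold higher and 4432 lower. Leaving out arrays gave 79 to 448 higher and 1 to 480 lower.

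For the 6C time course, the counts above and below day 0 were 1718 and 1263 with the filter. There were 583 above with degree 2 and run as a fixed block, and 156 and 38 at day 21 without the iPS array. The lower count was 911 with quantile normalization, 883 with an intensity trend and 879 with the untreated mean as day 0. Within run 1, 3028 clusters were over 2-fold above and 2119 below at day 21. Leaving out arrays gave 98 to 459 above and 38 to 284 below, with change taken from the first day left and direction at the last. Without the iPS array, where day 21 was the last day, the change turned sign for Mecom (0.84), Anxa8 (0.18), Magel2 (-0.24), Ttr (-0.35) and Dsg3 (2.54). Without day 0, where the change was taken from day 2, it did so for Tek (-0.61) and Krt17 (-0.00927). It also did so for Ddx58 (-0.14) with degree 2 and run as a fixed block, which changes the curve and the block together. With other arrays left out, the far ends of their ranges were -3.81, -3.00, 2.51, 2.22, -2.92, 5.55 and 2.65 in the order from Mecom to Krt17. Over 89 named genes and their alternatives, 1097 values kept direction and call, 408 lost the call and 8 turned sign; over 77 in iPS against untreated cells, 496 kept both and 197 lost the call.

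The shares of rises and falls begun by day 5 were 41.8% and 23.0% with degree 2, 74.2% and 10.7% with the square root of day, 79.1% and 32.9% at 1.5-fold, 40.0% and 6.67% at 3-fold, and 47.6% and 29.3% with quantile normalization. Falls stood at 13.7% with deposited values in place of the curve, and rises at 52.4% with the untreated mean as day 0. In each, a larger share of rises than of falls had begun by day 5.

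At day 5 in both lines, centring gave 334 higher and 259 lower clusters where the other tested settings gave 0; without a test 6C had 3407 and 1367 and 1B 2215 and 2955. After withdrawal, the returned shares of rises and falls were 80.2% and 74.1% with centring, 87.9% and 80.1% with the filter, 66.1% and 54.2% for clusters chosen in 6C (most of which had not changed over 2-fold the same way in 1B, so these shares say little of return), 84.4% and 77.9% with the untreated mean as baseline, and 79.4% and 68.8% at 1.5-fold; rises were 80.0% with quantile normalization, and falls 77.3% at 3-fold and 63.9% for clusters over 2-fold in both lines.

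With secondary iPS cells and 1B day 0 as the axis, progress over lower clusters was 0.46 for 6C day 5 and 0.87 for day 21, and over higher clusters 0.063 after withdrawal. Over called clusters without 6C day 0 it was 0.67 (higher) and 0.81 (lower) for 6C day 21, 0.44 (higher) for 1B day 5 and 0.051 (higher) after withdrawal. With the filter, 1890 clusters differed between the iPS arrays, and 2543, 1518 and 1766 between the untreated pairs.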

Other observations

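Of the 5 genes named as lowest in 6C at day 0 against parental cells, some were higher in the middle of the 6C series than at its start, which was not tested. Choosing genes by a low value in the day 0 array itself favours such a difference. Dpt, a dermal matrix gene, stood at 10.95 in parental cells, 5.51 in 6C at day 0, 9.98 at day 8 and 4.08 at day 16. Egfl6 stood at 10.41, 5.24, 11.32 and 8.62 in the same arrays, and Cxcl15 at 11.49, 5.56, 9.46 and 3.30. Comp, at 11.90 in parental cells, stood at 6.34 at day 0 and 6.59 at day 8, and Thbs4, at 11.82, stood at 5.86, 7.68 and, at day 16, 4.89. Imprinted genes included Phlda2, which was 5.54 in 6C at day 0, 5.90 at day 21 and 9.40 and 9.26 in the iPS arrays (iPS against untreated 4.05, SE 0.27).

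Other lists had fewer calls between iPS and untreated cells. The BMP list had 5 of 22 genes lower (6 lower and 1 higher adjusted over the list alone), glycolysis 2 of 14 higher (4 adjusted over the list alone), and macrophage and blood genes 1 of 16 lower (2 lower and 1 higher adjusted over the list alone). Imprinted genes had 1 of 13 higher and 1 lower (2 and 4 adjusted over the list alone), endothelial genes 2 of 16 higher and 1 lower (3 and 1), trophoblast genes 2 of 13 higher (3, with 1 lower) and housekeeping genes 1 of 10 higher (2, with 2 lower). The counts were the same adjusted over the list alone for p53 targets (2 of 18 lower), neural genes (3 of 18 higher, 1 lower), endoderm (1 of 16 higher), muscle (1 of 15 higher), keratinocyte genes (2 of 19 higher) and the reprogramming factors (2 of 4 higher). None of 19 oxidative phosphorylation genes and none of 14 interferon genes was called by limma, where 6384 of all clusters had an unadjusted p under 0.05. By camera with the preset correlation the BMP, glycolysis, oxidative phosphorylation, macrophage and reprogramming factor lists shifted (adjusted p = 2.49e-04, 0.0047, 0.0015, 0.039 and 0.015). In that order they had adjusted p = 0.44, 0.47, 0.44, 0.43 and 0.44 with an estimated correlation.

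Random orders of the days were fitted to the 6C series as a test of chance, set before its result was seen. Of 100 orders, the real one included, 1 gave as many calls as the real 1485, and the highest of the others gave 4. The number of calls thus depended on the order of the days. Random orders leave real change between days in the error, so the test does not show how many calls are false. It says nothing of the runs.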
